A study of Homo sapiens with 26 samples.

How the data were processed

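CUT&RUN libraries of HN-6 cells and of the SMYD3 knockout line 5-3, all exposed to interferon-β at 1000 U/ml for 24 h, were prepared with an EpiCypher kit per the labels. Sequencing libraries used a TruSeq ChIP kit for the siRNA experiment and an IDT 2S Plus kit for the knockout experiments. Of 26 samples, 22 come with a peak list, and the 4 IgG control samples come without one and were used by the authors only as the background of peak calling. The submitters' processing notes name bcl2fastq, Bowtie (no versions) and the hg38 build. The names of the deposited files state that peaks were called per library in a broad mode, on reads with duplicates removed, against 1 IgG library of HN-6 cells, which also served as background for the knockout line. The peak caller and its thresholds are not given in the sources used here.

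The unit of the values in the deposited lists is other than a signal: each of the 3 columns holds the chromosome, start or end of a peak, with no height, score or p-value. All positions lie on a grid of 1000 bp, the shortest peak is 5000 bp and the shortest gap 2000 bp. No pair of the 22 lists was identical (0 identical pairs). Read depth is unknown, so that a gene without a peak was not called in that library and is not shown to lack the mark. Groups were taken from the sample titles. The names of the siRNA files carry H3K4me3 where the titles and antibody fields say H4K20me3, and the titles were followed, with a check of their similarity to the other libraries given among the closing observations.

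Peaks on chromosomes 1 to 22 and X were set against 19974 protein-coding genes of the GRCh38.p14 annotation. The annotation at hand gives no strand, so the planned window around the 5′ end was replaced by windows of 1 kb on either side of both annotated gene ends, with an overlap of at least 1 bp. A marked gene may therefore have its peak at the 3′ end. Since no score is given, the planned ranking of peaks by score became a ranking by width, the planned fallback, with ties broken at random under a fixed seed. Per library, the number of peaks, covered length after merging, number of marked genes, median peak width, percent of peaks at a gene end and percent of covered length on chromosome 19 were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Groups were compared by exact two-sided permutation tests of the difference of means over 20 relabellings, with Benjamini-Hochberg adjustment over the 18 tests of these 6 measures in 3 comparisons. The comparisons were knockout against parental for H4K20me3 and H3K4me3, and siSMYD3 against siNC for H4K20me3. Replicate numbers were not treated as pairs.

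A gene, or a region from the merged peaks of the 6 libraries, was called lost or gained by the rule of 3 of 3 libraries against 0 of 3. The lost (or gained) share within each gene list was compared with the rest of its background by two-sided Fisher's exact tests. The background for losses was genes marked in all control libraries, and for gains genes marked in none. Adjustment was over 91 tests that had a member in the background. The 16 lists were interferon-stimulated genes, antigen processing and presentation, interferon signalling, nucleic acid sensing, cytokines and chemokines, chromatin repression, squamous epithelial genes, cell cycle genes, immune cell markers, fibroblast and endothelial markers, cancer-testis and germline genes, zinc finger genes on any chromosome, zinc finger genes of chromosome 19, clustered protocadherins, ribosomal protein genes and olfactory receptors. All 1722 list genes were found in the annotation. The number of marked list genes per library was also compared between groups in 48 exact permutation tests. SMYD3 antibody peaks were compared with the single knockout library as counts, with a 95% Wilson interval for shares, and list membership by 32 Fisher's exact tests. Overlaps between gene sets were tested in 4 Fisher's exact tests over the genes able to be in both sets. Library similarity was the base-pair Jaccard index, tested by exact permutation.

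Named genes followed a rule: 9 genes always (among them SMYD3, UHRF1, IRF9, IFIT1, ISG15, CXCL10 and ZNF274), up to 4 lost and 4 gained genes per list in order of the mean rank of peak width within libraries, the 10 leading lost and 10 leading gained genes over all genes in that order, and the 3 longest lost and gained regions. Groups, comparisons, tests, lists, this rule and the first set of alternatives were fixed before the data were examined. Alternatives were windows of 500 bp and 2.5 kb, whole genes, an overlap of 200 bp, the wider 50% of each library's peaks, an equal number of the widest peaks in each library, the rules of 2 of 3 against 0 and of 3 of 3 against up to 1, all annotated genes, 1 gene per 500 kb, joining peaks within 1 kb, a common width threshold, a blocked test by replicate number and leaving out each library. Leaving out chromosomes 1 and 3, leaving out chromosomes 13, 14, 15 and 18, and restricting to genes marked in all siNC libraries were added after seeing the data, as was the share of the peaks at the ends of lost or gained genes that the libraries of the other group covered, averaged over all pairs of libraries.

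The calls were tested on simulated data in which genes were planted as lost or gained in the real lists and each library kept 95.0% of its peaks at random. The rule recovered 86.9%, 89.0% and 86.1% of planted losses and 89.0%, 89.0% and 83.2% of planted gains in the knockout H4K20me3, knockout H3K4me3 and knockdown comparisons, with at most 1 false loss and 3 false gains among 19974 genes. Recovery of losses was set by this design (85.7% expected). Real replicates differ more than such copies (mean Jaccard index 0.477 among parental H4K20me3 libraries). These values therefore check the code and do not measure the error of the rule in the real libraries. For the first control library of each comparison, the number of overlapped windows at the lower-coordinate gene end equalled that from bedtools 2.31.1 (difference 0). Windows were not compared individually.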

Results

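The series profiled chromatin in HN-6, an established HPV-negative head and neck squamous carcinoma line, by CUT&RUN, in which an antibody directs nuclease cleavage to the chromatin it binds. The parental line was compared with 5-3, a derived line in which the lysine methyltransferase SMYD3 was knocked out. In a separate experiment HN-6 cells received a control siRNA (siNC) or an siRNA against SMYD3 (siSMYD3) for 72 h. All cells were exposed to interferon-β at 1000 U/ml for 24 h before collection, so that no library measures the unstimulated state. Antibodies recognised H4K20me3, a mark of compacted heterochromatin, H3K4me3, a mark of active promoters, and SMYD3 itself. Peak lists of 22 libraries in 8 groups were analysed, with 3 libraries in each group except SMYD3 in the knockout line, which has 1. The labels describe the 3 libraries of a condition as biological replicates. The lists hold the positions of broad peaks on hg38 and no read counts, so the depth behind each list is unknown. A gene was called marked when a peak overlapped the 1 kb on either side of either annotated end. Lost denotes a gene marked in 3 of 3 control libraries and 0 of 3 SMYD3-depleted libraries, and gained denotes the opposite. With 3 libraries against 3 no two-sided exact permutation test can give a p below 0.1, and no difference in library totals can pass a threshold of 0.05.

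SMYD3, the targeted gene (chromosome 1, 245749347 to 246507279), carried H3K4me3 at its ends in 3 of 3 parental and 3 of 3 knockout libraries, under peaks of 14.3 ± 5.13 kb and 12.7 ± 3.06 kb (mean ± SD, n = 3). H3K4me3 at these ends does not check whether SMYD3 protein was lost. No H4K20me3 library had a peak at the ends of SMYD3. The SMYD3 antibody had none there either, in the parental line or in the knockout. The strength of the siRNA knockdown is not given in the sources used here.

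In the knockout line H4K20me3 was listed over much less of the genome than in parental HN-6, and zinc finger genes retained it more often than other genes. Parental libraries had 45094 ± 2568 H4K20me3 peaks covering 468.7 ± 55.3 Mb (mean ± SD, n = 3), against 11690 ± 825 peaks and 135 ± 8.75 Mb in the knockout, 3.86-fold fewer peaks over 3.47-fold less sequence. Marked genes numbered 2407 ± 231 and 1250 ± 99.6, a 1.93-fold difference. Of the 1465 genes marked in all 3 parental libraries, 528 (36.0%) were lost, and 55 of the 16544 genes marked in no parental library were gained. Chromosome 19, which holds the main zinc finger clusters, took 2.73 ± 0.276% of the covered length in parental cells and 6.66 ± 0.489% in the knockout. Its share was 9.01 ± 0.230% in siNC and 8.58 ± 0.164% in siSMYD3 libraries. A share above that of parental libraries was thus not particular to the knockout.

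**Figure D1:**
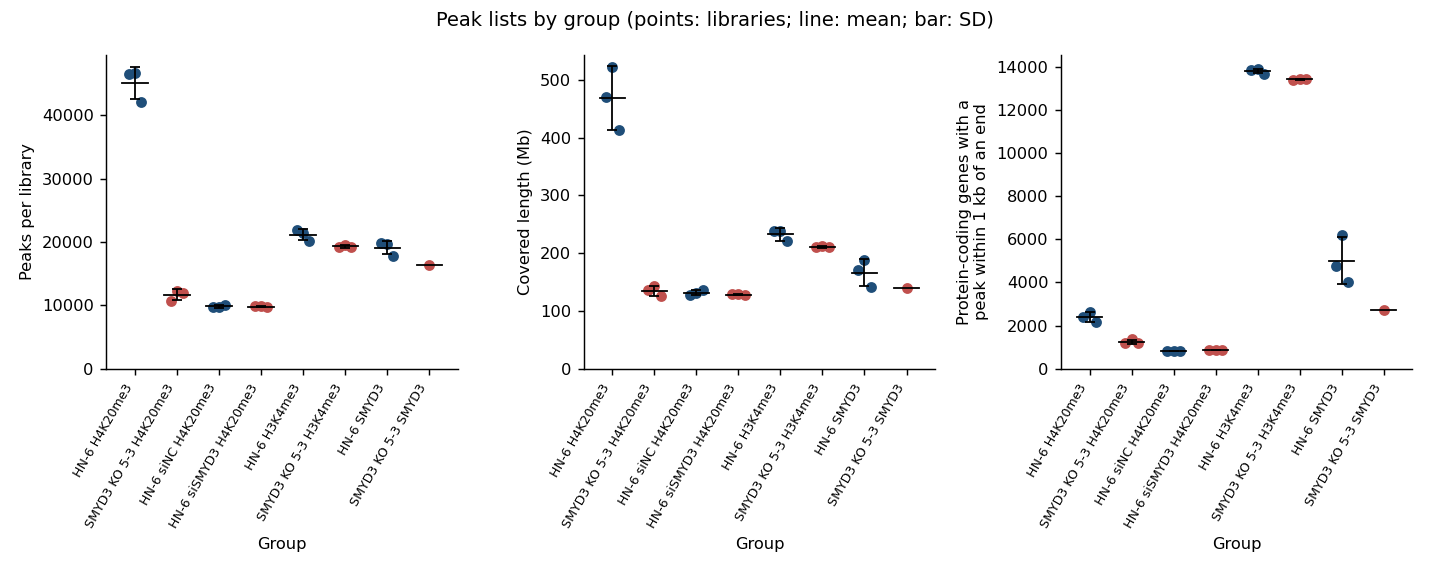
Peaks per library, covered length (Mb) and protein-coding genes with a peak within 1 kb of an end for each of the 8 groups; points are libraries (blue, control cells; red, SMYD3 knockout or siSMYD3), lines are means and bars SD. The 3 parental H4K20me3 libraries lie between 42132 and 46690 peaks, above the knockout libraries (10759 to 12331) and above the siNC libraries of the same cell line (9691 to 10101).

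Among interferon-stimulated genes, 5 of the 16 marked in all parental libraries were lost, a share (31.3%) close to that of other genes (36.1%). They included EPSTI1, an interferon-induced gene of epithelium and stroma (chromosome 13, 42886388 to 42992241, 28 ± 10.4 kb of H4K20me3 in parental cells), the helicase gene DDX60L (14.7 ± 4.04 kb), the nuclear body gene SP110 (11.7 ± 0.577 kb) and TRIM5, which encodes a restriction factor of retroviruses (9.33 ± 1.15 kb). CXCL10, the interferon-induced chemokine that attracts T cells (chromosome 4, 76021118 to 76023497), was lost from a peak of 9.33 ± 2.52 kb, as was IL18, a cytokine of the interleukin-1 family (7 ± 1.73 kb). These were the 2 lost of 6 cytokine and chemokine genes. RFX5, a regulator of MHC class II transcription, was the single gene of antigen presentation marked in all parental libraries and was lost (8.33 ± 1.53 kb). IFIT1 was marked in 1 parental and 0 knockout libraries, and IRF9, ISG15 and UHRF1 in none.

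Zinc finger genes kept H4K20me3 more often than other genes. Of 319 marked in all parental libraries, 18 (5.64%) were lost, against 44.5% of the remaining genes (odds ratio 0.0746, adjusted p = 1.71e-43 by Fisher's exact test). On chromosome 19 the loss was 6 of 216 (2.78%, against 41.8% of the remaining genes of all chromosomes, odds ratio 0.0398, adjusted p = 7.26e-35 by Fisher's exact test). Of all genes so marked on chromosome 19, zinc finger genes included, 23 of 280 (8.21%) were lost. ZNF274, which recruits the H3K9 methyltransferase SETDB1 to such clusters (chromosome 19, 58183061 to 58213562), lay under 265 ± 0.577 kb of H4K20me3 in parental cells and 213 ± 15.9 kb in the knockout, marked in 3 of 3 libraries of each. Exceptions were ZNF552 (chromosome 19, 57807082 to 57814913), ZNF439, ZNF729 and ZNF691, all lost. Neither chromosome nor peak width was matched between zinc finger genes and the rest. Of parental peaks of 5 kb, 86.6% were overlapped by no knockout library, against 0.417% of peaks of 100 kb or more. Retention at zinc finger genes was therefore not separated from the width of their peaks. Olfactory receptor genes, silent outside sensory neurons, went the other way. They lost the mark at 16 of 22 genes (72.7% against 35.5%, odds ratio 4.85, adjusted p = 0.00937 by Fisher's exact test), among them OR7G3 (chromosome 19, 9126012 to 9126950, 53 ± 2.65 kb), OR4C6, OR2L5 and OR2L2.

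**Figure D2:**
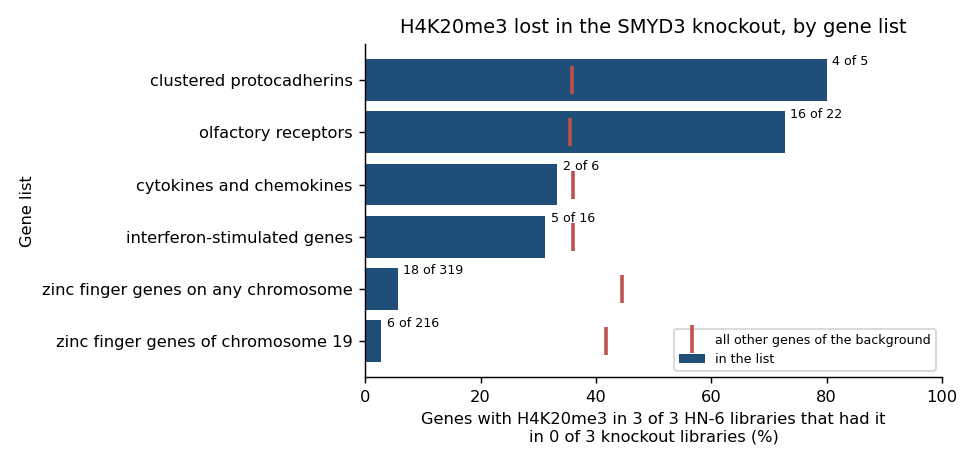
Share of genes with H4K20me3 in 3 of 3 parental libraries that had it in 0 of 3 knockout libraries (%), for gene lists with at least 5 such genes; bars are the list, red ticks all other genes marked in parental cells, and labels give lost of marked genes. Zinc finger genes lost the mark at 18 of 319 and olfactory receptors at 16 of 22.

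Clustered protocadherins, cell adhesion genes on chromosome 5, lost 4 of 5 genes marked in all parental libraries (adjusted p = 0.558 by Fisher's exact test). These were PCDHA2, PCDHA3, PCDHA4 and PCDHA5, which share a common 3′ end. The other lists had few genes so marked. Lost were 1 of 3 squamous epithelial genes, the replication gene GINS1 of 2 cell cycle genes, the natural killer receptor gene KLRD1 of 1 immune cell marker, TEK and COL3A1 of 4 fibroblast and endothelial markers, the meiotic gene SYCP1 of 3 cancer-testis and germline genes and RPL17 of 1 ribosomal protein gene. None of 2 interferon signalling genes, 1 nucleic acid sensing gene and 2 genes of chromatin repression was lost. A lost gene has no knockout peak at its ends, but the parental peak given with it may persist further away: at 164 of the 528 lost genes (31.1%) at least 1 knockout library overlapped it. The leading losses over all genes by the mean rank of parental peak width were of this kind. Knockout peaks covered on average 50% of the parental peak of ALCAM, an adhesion molecule (chromosome 3, 105366909 to 105576900, 81.7 ± 6.03 kb), 91.9% of that of LYPD5 (261 ± 3.79 kb), 78.5% for TMEM154, 65.6% for TRIM16, 56.7% for RNGTT, 77.4% for VN1R4, 86.8% for ZNF552 and 55.4% for OR7G3, and 10.3% for KCTD4 and 0.289% for RGS18. Of 22710 regions covered in all parental libraries, 14749 (64.9%) were lost. The largest held no protein-coding gene and lay on chromosome 6 (92403001 to 92553000, 137 ± 7 kb covered), chromosome 4 (180279001 to 180447000, 125 ± 20.2 kb) and chromosome 1 (191824001 to 191956000, 115 ± 5.51 kb).

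The parental and knockout ranges did not overlap for peaks, covered length or marked genes (exact permutation p = 0.1 each, adjusted p = 0.138 over 18 such tests). When every library was reduced to an equal number of its widest peaks, 121 genes were lost and 141 gained and marked genes were 3.38% more numerous in the knockout (exact permutation p = 0.6), and without parental replicate 3 the lost genes were 864. The olfactory receptor call missed the threshold with an equal number of peaks and with up to 1 knockout peak allowed. It also did so with all annotated genes as background and without chromosomes 1 and 3 (Fisher's exact adjusted p of its alternatives 0.000319 to 0.196). That span leaves out 1 gene per 500 kb, where its odds ratio was infinite. The call missed the threshold there too, as the 2 lists that passed were those of zinc finger genes. Both zinc finger calls held in all 12 alternatives (Fisher's exact adjusted p up to 4.43e-05 for all chromosomes and 0.000390 for chromosome 19), none of which matched peak width.

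Genes that gained H4K20me3 in the knockout included 3 of 47 interferon-stimulated genes: GBP3 and GBP5, interferon-induced GTPases (chromosome 1, 89006680 to 89022866, 22.3 ± 7.23 kb, and 89256189 to 89272860, 12 ± 5.29 kb), and TNFSF10, which encodes the death ligand TRAIL (chromosome 3, 172505508 to 172523430, 12.7 ± 5.03 kb). This share, 6.38% against 0.315% of other genes, gave an odds ratio of 21.6 (adjusted p = 0.00937 by Fisher's exact test). The antiviral gene ZC3HAV1 (8 ± 0 kb) was 1 of 19 nucleic acid sensing genes gained (adjusted p = 0.558 by Fisher's exact test). No gene was gained in the other 14 lists, which include 158 zinc finger and 322 olfactory receptor genes. At 20 of the 55 gained genes (36.4%) a parental peak overlapped the knockout peak away from the gene ends. The gained genes were concentrated in a pair of segments. Of 55, 22 lay on chromosome 1 between 77282019 and 101996926 and 21 on chromosome 3 between 158696892 and 196338388, among them OLFM3, SH3GLB1, CLCA4, C1orf52, NCEH1, NAALADL2 and RARRES1. The widest gained region lay on the other arm of chromosome 1 (228605001 to 228648000, 35.3 ± 7.23 kb), followed by regions within DPYD (chromosome 1, 97588001 to 97631000) and on chromosome 3 (158764001 to 158799000).

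In 5 Mb bins holding a gained gene (22 bins), the median log2 ratio of H4K20me3 coverage, knockout over parental, was 0.39, against -1.60 in the other 579 bins. A higher H4K20me3 ratio follows from the choice of these bins by genes gained in the same libraries. The same bins had a higher ratio for the SMYD3 antibody (0.99 against -0.38) and for H3K4me3 (0.19 against -0.09). Without chromosomes 1 and 3, an alternative added after the data were seen, 11 genes were gained and no interferon-stimulated gene (odds ratio 0). The interferon call also missed the threshold with 500 bp or 2.5 kb around gene ends and with 1 gene per 500 kb, its adjusted p spanning 3.40e-05 to 1 over the alternatives. Without knockout replicate 1 the gained genes were 108, and the 252 gained regions became 699, 398 or 433 without knockout replicate 1, 2 or 3.

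**Figure D3:**
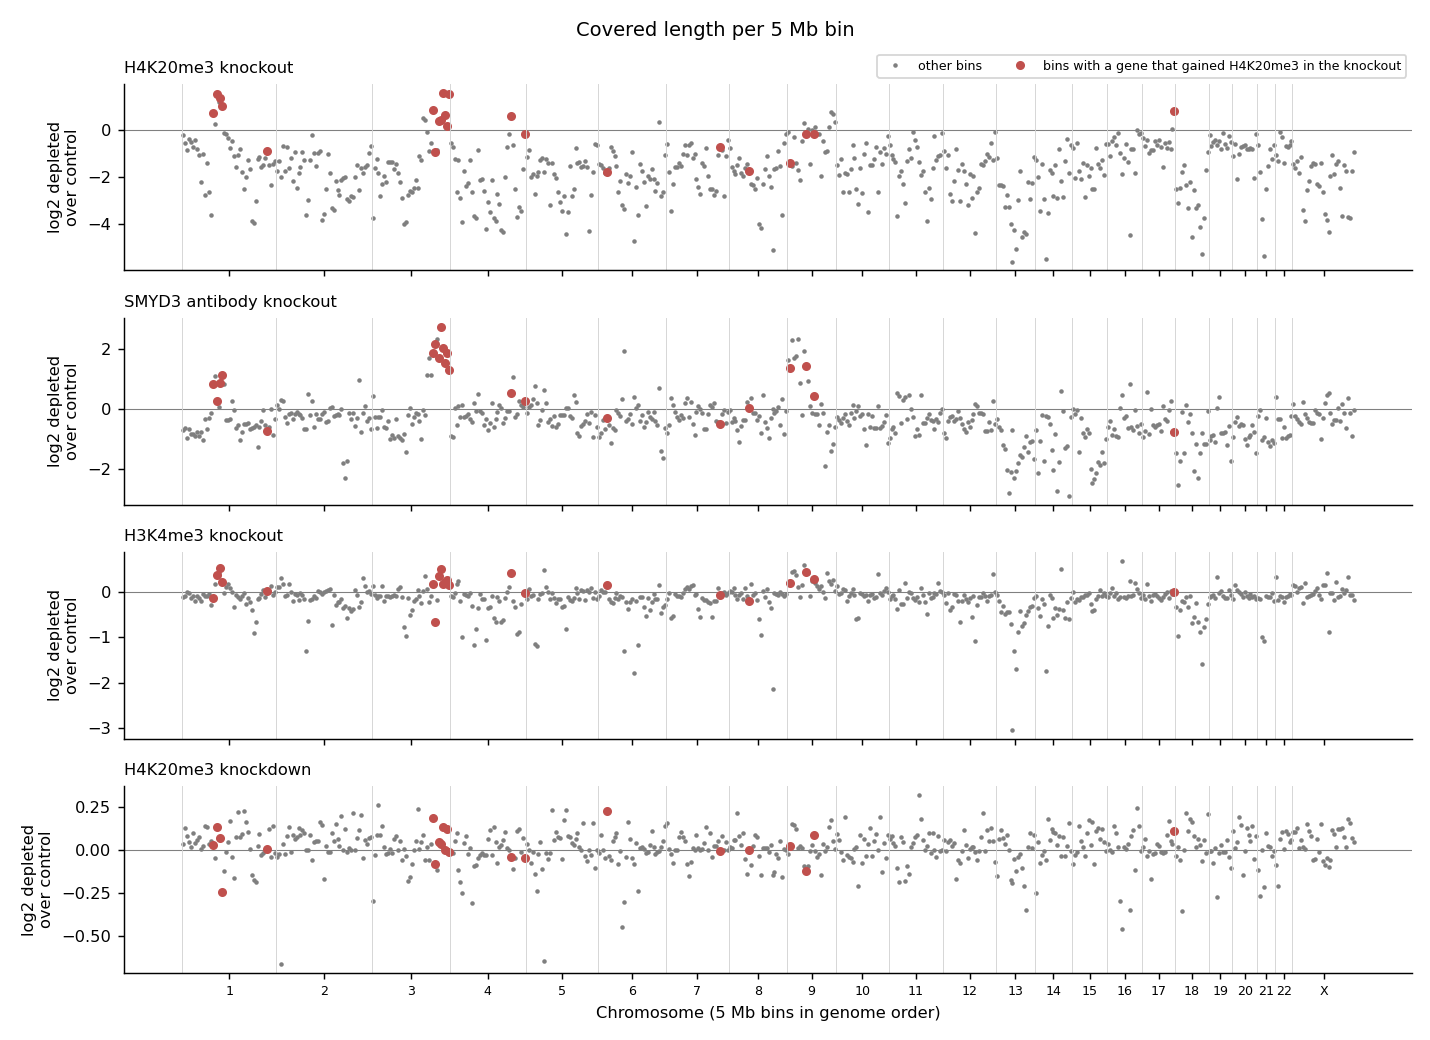
Log2 ratio of covered length, depleted over control, in 5 Mb bins in genome order for H4K20me3 in the knockout, the SMYD3 antibody in the knockout, H3K4me3 in the knockout and H4K20me3 after siSMYD3; red points are the 22 bins that hold a gene gaining H4K20me3 in the knockout. These bins stand above the others in the 3 knockout panels (medians 0.39, 0.99 and 0.19) and not after siSMYD3 (0.03 against 0.02), on a narrower axis. For H4K20me3 in the knockout this follows from how the bins were chosen.

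H3K4me3 was called lost or gained at few genes in the knockout, and no interferon-stimulated gene was among those lost. These calls rest on the presence of a peak and do not count a change in its width. All 74 interferon-stimulated genes marked in the 3 parental libraries retained the mark in at least 1 knockout library, as did 27 interferon signalling and 21 nucleic acid sensing genes. Other genes lost it at 2.08%, so that interferon-stimulated genes were not set apart (Fisher's exact p = 0.409 before adjustment). IRF9, a transcription factor of the interferon response, was marked in 3 of 3 libraries of each line (10.7 ± 0.577 and 5.67 ± 1.15 kb in parental and knockout cells), as were IFIT1 (40.0 ± 4.58 and 22.3 ± 9.29 kb) and ISG15 (35.3 ± 0.577 and 34.3 ± 0.577 kb). CXCL10 was marked in 0 parental libraries and 1 knockout library, and UHRF1 in none. Of 13521 genes marked in all parental libraries, 280 (2.07%) were lost. They included HOXB4, a homeobox gene (chromosome 17, 48575507 to 48578350, 59 ± 0 kb), HLA-DMA, which loads peptides onto MHC class II and was the 1 lost of 28 antigen presentation genes (8.67 ± 0.577 kb), and CD4, the T cell co-receptor gene and 1 of 10 immune cell markers (18.3 ± 2.89 kb). SLITRK3, THTPA, ACER1, PCDH11X, AGMO, TM4SF5, PARP15, ATP12A and THSD7A completed the leading losses. Knockout peaks overlapped the parental H3K4me3 peaks of 44 of the 280 lost genes (15.7%) away from the gene ends, covering 74.6% of that of HOXB4.

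H3K4me3 was gained at 44 of 5910 unmarked genes, more often at zinc finger genes than at others (8 of 91, 8.79% against 0.619%, odds ratio 15.5, adjusted p = 7.91e-06 by Fisher's exact test). ZNF750, a regulator of epidermal differentiation (chromosome 17, 82829434 to 82840022, 21.3 ± 5.77 kb), ZNF626, ZNF875 and ZNF485 were examples. On chromosome 19, 4 of 54 were gained (7.41% against 0.683%, odds ratio 11.6, Fisher's exact adjusted p = 0.00978), ZNF492 and ZNF208 besides ZNF626 and ZNF875. COL17A1, the hemidesmosomal collagen of basal keratinocytes, was the 1 gained of 20 squamous epithelial genes (10.3 ± 0.577 kb), and PCDHA10 the 1 of 24 protocadherins. By the rank of peak width the leading gains also held FOXL1, a forkhead factor gene (chromosome 16, 86578549 to 86583478, 31 ± 0 kb), SLURP1, a secreted keratinocyte protein (22 ± 0 kb), FGF13, the neural factor gene SOX1, LRATD1 and CRLF2. Parental peaks overlapped the knockout peaks of 10 of the 44 genes (22.7%) away from their ends, covering 74.2% of that of FOXL1 and 77.3% of that of SLURP1. Zinc finger genes lost H3K4me3 at 1 of 401 (ZNF385B, odds ratio 0.115, Fisher's exact adjusted p = 0.0483). Losses were 0 of 20 cytokine, 0 of 40 chromatin repression, 0 of 34 squamous, 0 of 43 cell cycle, 0 of 8 fibroblast and endothelial, 0 of 12 cancer-testis, 0 of 185 chromosome 19 zinc finger, 0 of 22 protocadherin and 0 of 78 ribosomal protein genes and 1 of 14 olfactory receptors (OR5H1), and no other list had a gain. Regions lost numbered 1724 of 18840 (9.15%), led by chromosome 21 (19826001 to 19859000) and by CSMD3 on chromosome 8 (112490001 to 112516000). Regions gained numbered 442, led by TOX on chromosome 8 (59044001 to 59073000).

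Parental libraries had 21161 ± 857 H3K4me3 peaks over 232.6 ± 10.6 Mb and 13796 ± 106 marked genes, and knockout libraries 19306 ± 176 peaks over 210.8 ± 1.45 Mb and 13409 ± 27.5 marked genes (n = 3 each), without overlap of the ranges (exact permutation p = 0.1 each, adjusted p = 0.138). Both calls of gained zinc finger genes missed the threshold with 1 gene per 500 kb (adjusted p over the alternatives 6.02e-10 to 0.132 for all chromosomes and 3.91e-08 to 0.671 for chromosome 19), and the lost call did so in 8 of 11 alternatives (adjusted p 0.00104 to 1), without parental replicate 2 (odds ratio 0.217) and without knockout replicate 3 (odds ratio 0.302). The number of gained genes was 67 without parental replicate 1.

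After siSMYD3 the H4K20me3 lists were close to those after siNC. Zinc finger genes of chromosome 19 were marked at 216 ± 1.53 genes with siNC and 215 ± 0.577 with siSMYD3, and ZNF274 lay under 265 ± 2.08 and 249 ± 21.1 kb in 3 of 3 libraries of each. None of the 6 interferon-stimulated genes marked in all siNC libraries was lost, and none of the 70 marked in no siNC library was gained. SMYD3, UHRF1, IRF9, IFIT1, ISG15 and CXCL10 were unmarked in all 6 libraries. A gene without a siNC peak could not be called lost. Of 732 genes marked in all siNC libraries, 4 were lost: the helicase gene MCM9 (chromosome 6, 118813455 to 118935159, 12.3 ± 1.15 kb), WDR27 (11 ± 0 kb) and the adjacent DHX32 and FANK1 on chromosome 10 (125836337 to 126009592, 10.7 ± 0.577 kb over each). The 10 gained of 19045 genes were ZSCAN21 (14 ± 0 kb), ARL14 (13.3 ± 0.577 kb), ANKRD13D, C2orf69, POLR3E, EPHA7, KYAT3, FAM120B, ATP5MC3 and MYLK4. Away from the gene ends the other group had overlapping peaks at all 4 lost and 7 of the 10 gained genes. Regions lost numbered 75, the longest on chromosome 19 (21598001 to 21620000, 12.3 ± 7.09 kb), and 68 were gained, led by FMNL2 on chromosome 2 (152492001 to 152505000, 9.67 ± 2.89 kb).

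The siNC libraries had 9840 ± 227 peaks over 131.7 ± 3.98 Mb and the siSMYD3 libraries 9815 ± 68.5 peaks over 128.5 ± 0.369 Mb (exact permutation p = 1 and 0.3). Marked genes were 826.7 ± 5.69 and 852.7 ± 4.04, higher in 3 of 3 siSMYD3 libraries (exact permutation p = 0.1, adjusted p = 0.138), a difference of 3.15% that was 0% with all annotated genes (exact permutation p = 1). No gene list passed Fisher's exact test with an adjusted p under 0.05, and the smallest unadjusted Fisher's exact p was 0.152. No list had a lost or gained member, and 4 lost and 10 gained genes leave such tests little power. Lost genes were 8 without siNC replicate 1, siNC replicate 3 or siSMYD3 replicate 3, and gained genes 16 without siSMYD3 replicate 1 and 20 without siSMYD3 replicate 2. Leaving out any 1 of the 6 libraries gave 140 to 195 lost and 107 to 159 gained regions, and the difference in peaks changed sign without siNC replicate 3 (1.09%) or siSMYD3 replicate 3 (0.120%).

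The parental H4K20me3 lists also covered more sequence than the siNC lists of the same cell line (468.7 ± 55.3 and 131.7 ± 3.98 Mb, n = 3 each). The base-pair Jaccard index, the shared length over the combined length, averaged 0.237 between parental and siNC libraries, 0.189 between parental and knockout libraries and 0.314 between knockout and siNC libraries, and it is bounded by the unequal lengths of the lists in the pairs with parental libraries. Of the 732 genes marked in all siNC libraries, 97.1 ± 0.394% were marked in parental libraries and 80.6 ± 4.03% in knockout libraries. Losses in the knockout were 74 of 695 (10.6%) among parental genes also marked in all siNC libraries and 406 of 637 (63.7%) among those marked in no siNC library. The 2 experiments used different library kits, and the kit cannot be separated from the experiment. Within a comparison, libraries of a group shared more sequence with each other than with the other group, by 0.311 for H4K20me3 in the knockout (0.499 within, 0.189 between), 0.111 for H3K4me3 (0.861 and 0.749) and 0.0107 after siSMYD3 (0.769 and 0.759; exact permutation p = 0.1 each).

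**Figure D4:**
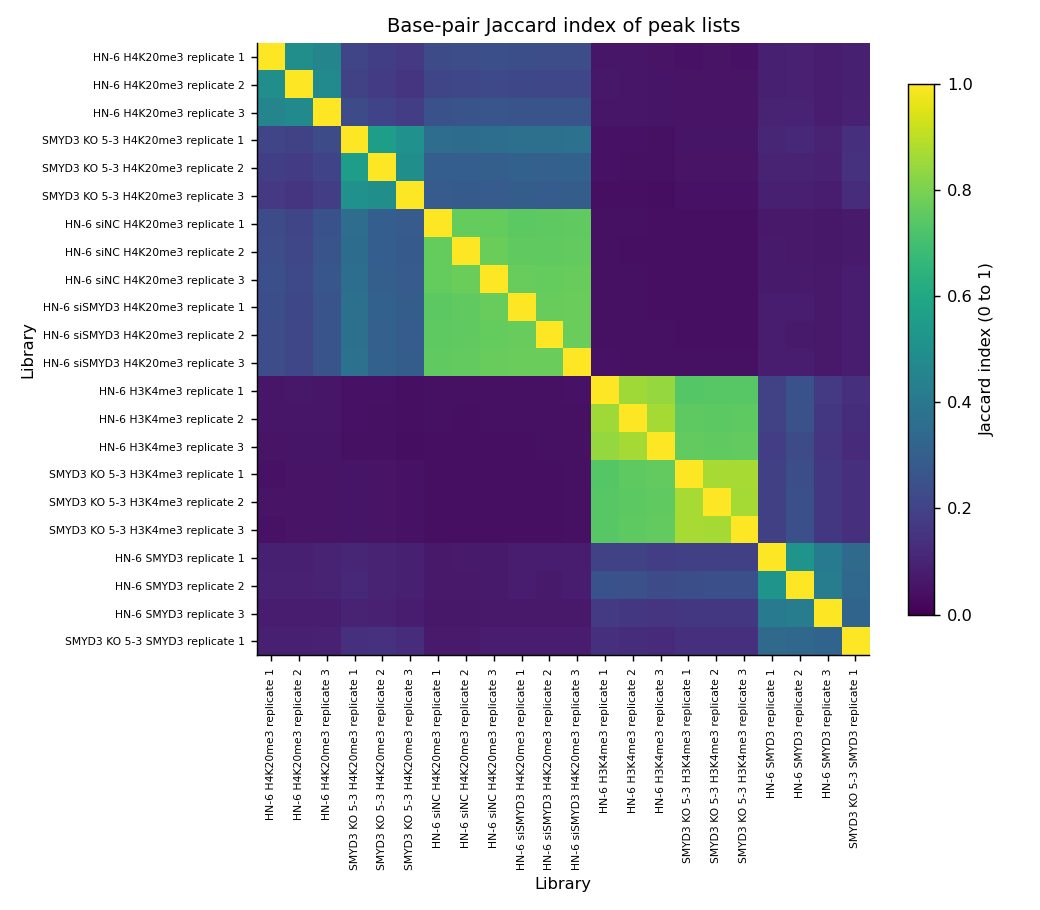
Base-pair Jaccard index (0 to 1, colour) for each pair of the 22 libraries, listed by antibody and group on both axes. The siNC and siSMYD3 libraries form a single block (mean 0.759 between groups), apart from parental H4K20me3 (0.237 with siNC), and H3K4me3 libraries form another (0.749 between parental and knockout).

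Most genes with SMYD3 antibody peaks at their ends carried H3K4me3, genes of squamous epithelium had such peaks more often than others, and most bound genes were also listed in the knockout line. Of all SMYD3 peaks in parental libraries, 22.0 ± 3.83% lay at a gene end (n = 3). Peaks at gene ends were found in all 3 parental libraries at 2769 genes, of which 92.0% carried H3K4me3 in all parental libraries (67.7% of all genes) and 11.6% H4K20me3 (7.33%). Of these, 1686 (60.9%, 95% Wilson interval 59.1 to 62.7%) also had a peak in the single knockout library and 1083 (39.1%) had none. H4K20me3 was carried by 14.0% of the 1686 and 7.94% of the 1083, and H3K4me3 by 91.6% and 92.7%. The excess of H4K20me3 over all genes thus lay mainly at genes that also had a knockout peak. These shares were not tested. Squamous epithelial genes were bound at 21 of 56 (37.5% against 13.8%, odds ratio 3.75, adjusted p = 4.75e-05 over 32 Fisher's exact tests), 3 of them without a knockout peak, which is 5.36% of the list against 5.42% of other genes (odds ratio 0.987, exact adjusted p = 1). Of the 53 clustered protocadherins 22 were bound, each also in the knockout (odds ratio 4.44, Fisher's exact adjusted p = 4.66e-06). Members of this family can share an annotated end and are not independent in the test. Zinc finger genes (34 of 509, 6.68%, exact adjusted p = 2.64e-06), those of chromosome 19 (4 of 246, adjusted p = 3.41e-10) and olfactory receptors (9 of 390, adjusted p = 9.34e-14) were bound less often than other genes.

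Interferon-stimulated genes were bound at 17 of 77 (Fisher's exact adjusted p = 0.134), each also in the knockout. The share bound in all parental libraries and absent from the knockout was 0 of 77, against 5.44% of all other genes (Fisher's exact adjusted p = 0.0706). DDX60L, GBP3 and TNFSF10 had the antibody in 3 parental libraries and in the knockout, IFIT1 in 2 and the knockout, and IRF9, ISG15 and CXCL10 in none. Binding was found at 6 of 36 antigen presentation, 5 of 29 interferon signalling, 4 of 24 nucleic acid sensing, 10 of 42 cytokine, 7 of 41 chromatin repression, 12 of 44 cell cycle, 1 of 32 immune, 5 of 24 fibroblast and endothelial, 5 of 39 cancer-testis and 6 of 80 ribosomal protein genes, none past the threshold. Leading genes by width rank among those absent from the knockout, chosen after their values were seen, included CLDN4, a tight junction gene (chromosome 7, 73830996 to 73832690, 27.7 ± 9.29 kb), CYP24A1, which inactivates vitamin D (chromosome 20, 54143538 to 54173986, 26 ± 1 kb), IRF2BPL, ESRRA and C1orf105 (29 ± 3.46 kb). In the knockout library peaks covered 67.1% of the parental peaks of CLDN4, 80.8% of those of CYP24A1 and 42.0% of those of C1orf105 away from the gene ends, and overlapped those of 194 of the 1083 genes (17.9%). All but C1orf105 carried H3K4me3 in 3 parental libraries.

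Parental libraries had 19128 ± 1100 SMYD3 peaks over 166.4 ± 23.6 Mb (n = 3) and the knockout library 16339 over 139.4 Mb, and these totals were not tested. The Wilson interval covers counting error only. Of genes bound in a pair of parental libraries, the third parental library held 67.8% to 94.6% and the knockout library 50.3% to 58.6%. Without parental replicate 3 the genes absent from the knockout numbered 2031, and with the wider 50% of each library's peaks 593.

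Genes that lost H3K4me3 in the knockout were bound by the SMYD3 antibody less often than other H3K4me3 genes (16 of 280, with 52.8 expected by chance, odds ratio 0.256, adjusted p = 8.18e-10 over 4 Fisher's exact tests). Peak width was not matched in this test. Of parental H3K4me3 peaks, 41.7% of those of 5 kb were overlapped by no knockout library, against 0.846% of those of 20 to 49 kb. The low overlap was therefore not separated from the width of the H3K4me3 peaks. Bound here means a peak in all 3 parental libraries. Of these 2769 genes 1686 also had a peak in the knockout line, so the overlaps do not isolate binding that depends on SMYD3. Overlaps with the 1083 genes absent from the knockout were not tested. Genes that lost H4K20me3 were bound at 106 of 528, with 116 expected (odds ratio 0.838, exact adjusted p = 0.190). Among the 487 genes able to lose H4K20me3 and to gain H3K4me3, 227 lost H4K20me3. Of these 227 genes 2 gained H3K4me3, with 5.13 expected (odds ratio 0.248, Fisher's exact adjusted p = 0.0921). WDR27, DHX32 and FANK1 lost H4K20me3 both in the knockout and after siSMYD3, 3 of the 4 knockdown losses with 0.426 expected (odds ratio 26.2, exact adjusted p = 0.00859). DHX32 and FANK1 are neighbours under a common peak and count as separate genes in the test. With 500 bp or 2.5 kb around gene ends this odds ratio was 0, with whole genes 1.76, and the adjusted p over the alternatives spanned 0.00576 to 1. The overlap of lost H4K20me3 with SMYD3 binding passed the threshold with 2.5 kb (odds ratio 0.708) and with whole genes (0.530), and its odds ratio was above 1 with the wider 50% of peaks (1.11) or an equal number (1.30), at adjusted p from 9.37e-21 to 0.568. Whole genes also took the overlap of lost H4K20me3 with gained H3K4me3 past the threshold (odds ratio 0.267, adjusted p 0.00912 to 0.0927 over the alternatives). Genes are not independent replicates, and these tests count genes.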

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

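The tests in this part were chosen only after the results were seen. Exceptions were the permutation tests of marked genes and the alternatives with an equal number of peaks and with all annotated genes. For H3K4me3 and the siRNA libraries in 5 Mb bins, the prediction was written before the test. The bins themselves were set by the genes called gained in these data.

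Each knockout library had fewer genes with H4K20me3 than each parental library, and each siSMYD3 library more than each siNC library (exact permutation p = 0.1 each), although with all annotated genes the siRNA difference was 0% (exact permutation p = 1). The log2 ratio of genes with H4K20me3 at an end was -0.94 for knockout over parental HN-6 and 0.04 for siSMYD3 over siNC, a difference of -0.99, which was not tested. For peaks and covered length, where the siRNA groups overlap, the differences were -1.95 and -1.76, also not tested. With an equal number of peaks in each library, marked genes in the knockout were 3.38% more numerous than in parental cells (exact permutation p = 0.6).

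The H4K20me3 lists of the knockout line cover less of the genome than those of parental cells, and a technical source stays open. Of parental peaks of 5 kb, 86.6% were overlapped by no knockout library, against 0.417% of peaks of 100 kb or more, a difference of 86.2 percentage points, but wide peaks are overlapped more easily and the shares also fell with width for H3K4me3 (41.7% to 0%) and after siSMYD3 (31.3% to 0%), so that a lower sensitivity of the knockout libraries for short peaks cannot be told apart from a loss of the mark. Fewer copies of some chromosomes in the knockout line do not account for the whole of it, since without chromosomes 13, 14, 15 and 18 the lost share of genes was 33.3%, against 36.0% with them. Depletion of SMYD3 as the source cannot be told apart from the other differences between the lines by the siRNA experiment, where covered length differed by -2.44% and the strength of knockdown is not known. In addition, 406 of the genes lost in the knockout had a peak in no siNC library and could not be called lost after siSMYD3. That parental libraries cover more than siNC libraries of the same cell line (468.7 and 131.7 Mb) may reflect the different library kits, which was not tested.

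H4K20me3 gained in the knockout lies mostly on parts of chromosomes 1 and 3, and a candidate explanation is a higher copy number of these segments in the line 5-3. The bins that hold gained genes had a median log2 ratio higher by 1.37 for the SMYD3 antibody, with 1 knockout library (p = 0.00333, permutation by 601 circular shifts) and by 0.29 for H3K4me3 (p = 0.00333, the same permutation) than the other bins. These are antibodies against different targets, the shifts of bins do not measure variation between libraries, and the deposited lists allow no direct measure of copy number. For SMYD3 depletion itself, the difference after siSMYD3 was 0.00829 on the log2 scale (p = 0.682, permutation by the same shifts), and as the strength of knockdown is not known, this explanation cannot be told apart from no effect. None of the 55 gained genes was marked in more siSMYD3 than siNC libraries, while KYAT3 and ARL14, chosen after their values were seen, lie within the segments of chromosomes 1 and 3 and were among the 10 genes gained after siSMYD3.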

How the results depend on the processing

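Alternatives left out of the plan and chosen only after the data were seen were the exclusion of chromosomes 1 and 3, the exclusion of chromosomes 13, 14, 15 and 18 and the restriction to genes with H4K20me3 in all siNC libraries; the other alternatives were planned. For results that answer a comparison, 348 values kept their direction and their side of the threshold or stayed within 1.5-fold or 1 SD of the reported value, 15 were fixed by the setting, 78 moved further, 20 missed the threshold, 3 newly passed it and 9 changed direction. For named genes, 567 values kept the gene's call or, where it had none, stayed within 1 library of the reported difference in marked libraries, 129 did not and none changed direction. Peaks and covered length in the knockout kept their direction with a common width threshold, with main chromosomes only and without each library in turn (H4K20me3 peaks -74.3 to -68.4% and -74.9 to -73.0%, H3K4me3 peaks -9.07 to -8.27% and -10.8 to -7.24%). Joining peaks within 1 kb could not move these totals, as no gap is under 2000 bp, nor could the replicate block move a percent change. Marked genes after siSMYD3 differed by 0% with all annotated genes. Direction was also kept by both zinc finger calls for lost H4K20me3 and the low overlap of lost H3K4me3 with SMYD3 binding (odds ratio 0.229 to 0.514). Replicate numbers do not pair the libraries: correlations of their deviations from the group means in 10 kb bins were -0.0213 to 0.0261 over equal and unequal numbers, and in no comparison did every library correlate best with its own number. With the number as a replicate block, H4K20me3 peaks in the knockout differed by -74.1% (exact sign-flip permutation p = 0.25, the smallest possible). Depth is unknown and limits each statement about absent peaks. Where the cause is not given with a value it was not tested.

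With 500 bp around gene ends the interferon-stimulated gain had an odds ratio of 15.2, the loss of H3K4me3 at zinc finger genes 0.335 and the overlap of knockout and knockdown losses 0. With 2.5 kb these were 12.3, 0.119 and 0, the overlap of lost H4K20me3 with SMYD3 binding was 0.708 and 1 list passed after siSMYD3 (zinc finger genes gained). With whole genes, 1362 genes lost and 85 gained H4K20me3 in the knockout, 7 and 22 after siSMYD3, the odds ratio of H3K4me3 loss at zinc finger genes was 0.231, and the overlaps were 0.530 (SMYD3 binding), 0.267 (gained H3K4me3) and 1.76 (knockdown losses). With all annotated genes the counts were 2999 and 182 for H4K20me3 in the knockout, 725 and 193 for H3K4me3 and 37 and 25 after siSMYD3, more genes being counted, and the olfactory receptor loss was 3.07.

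With the wider 50% of each library's peaks, 345 genes lost and 28 gained H4K20me3 in the knockout, 106 gained H3K4me3, 3 gained H4K20me3 after siSMYD3 and 593 had SMYD3 antibody peaks absent from the knockout. Regions lost and gained were then 6906 and 158 (H4K20me3), 489 and 191 (H3K4me3) and 40 and 35 (siSMYD3), the zinc finger loss of H3K4me3 0.264 and the overlap of lost H4K20me3 with SMYD3 binding 1.11. With an equal number of peaks in each library, 121 genes and 1599 regions lost and 141 genes and 1221 regions gained H4K20me3, marked genes turned from fewer to 3.38% more in the knockout, the olfactory receptor loss was 10.9, 93 genes and 730 regions gained H3K4me3, its zinc finger loss was 0.139, the overlap with SMYD3 binding was 1.30 and the difference in SMYD3 peaks was 0 by construction. With a common width threshold, peaks differed by 1.11% after siSMYD3 and by -24.9% for the SMYD3 antibody.

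With 2 of 3 libraries against 0, a looser rule, 1223 genes and 25732 regions lost and 148 genes and 967 regions gained H4K20me3, 77 genes and 818 regions gained H3K4me3, and after siSMYD3 14 genes and 370 regions were lost, 31 genes and 294 regions gained and 1 list passed (zinc finger genes, 0 lost). With up to 1 peak allowed in the depleted group or the control group, 97 genes and 422 regions gained H4K20me3, 91 genes and 731 regions gained H3K4me3, 11 genes and 283 regions were lost and 23 genes and 249 regions gained after siSMYD3, the olfactory receptor loss was 4.07 and the zinc finger loss of H3K4me3 0.245. With 1 gene per 500 kb, which leaves fewer genes, 2 lists passed for H4K20me3 and 0 for H3K4me3, with odds ratios of 45.3 (interferon-stimulated gain), 0.564 (zinc finger loss of H3K4me3), 24.5 (zinc finger gain) and 30.3 (gain on chromosome 19).

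Without chromosomes 1 and 3, 11 genes gained H4K20me3, 2 lists passed, the interferon-stimulated odds ratio was 0, as all 3 genes lie there, and the olfactory receptor loss was 3.56. Without chromosomes 13, 14, 15 and 18 the zinc finger loss of H3K4me3 was 0.139. Among genes marked in all siNC libraries, 74 lost H4K20me3. Leaving out 1 library raises the counts by construction, since fewer libraries must meet the rule. Genes lost and gained were then 550 to 864 and 62 to 108 for H4K20me3, gained H3K4me3 51 to 67, and after siSMYD3 5 to 8 lost and 13 to 20 gained. Gained H4K20me3 regions were 289 to 699, regions after siSMYD3 140 to 195 lost and 107 to 159 gained, SMYD3 genes absent from the knockout 1213 to 2031, the zinc finger loss of H3K4me3 0.0914 to 0.302 and the difference in peaks after siSMYD3 -0.999 to 1.09%. The single SMYD3 knockout library could not be left out, and alternatives with an infinite odds ratio have no value (olfactory receptors with 1 gene per 500 kb, and the overlap of knockout and knockdown losses with an equal number of peaks). With 1 gene per 500 kb the olfactory receptor call missed the threshold, as the 2 lists that passed for H4K20me3 were those of zinc finger genes.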

Other observations

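The tests of the antibody labels and of other divisions of the libraries were chosen only after the results were seen.

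Loss of H4K20me3 in the knockout was uneven along the genome. Covered length in the knockout was 6.46% of that in parental cells on chromosome 13, 6.75% on chromosome 18, 11.8% on X and 14.3% on chromosome 14, and it was 70.9% on chromosome 19, 64.2% on chromosome 1 and 61.5% on chromosome 9. H3K4me3 had its lowest shares on chromosomes 13 (61.9%), 18 (64.5%) and 14 (72.8%), and reached 115% on chromosome 9. For the SMYD3 antibody the single knockout library stood at 25.1% of the parental mean on chromosome 13 and 23.4% on chromosome 18, and at 221% on chromosome 3 and 127% on chromosome 9.

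Per library, clustered protocadherins were marked by H4K20me3 at a mean of 18 genes in parental cells and 0.333 in the knockout, and olfactory receptors at 45.3 and 7. Zinc finger genes were marked at 337 and 298, and interferon-stimulated genes at 22 and 19. After siNC and siSMYD3 the means were 301 and 302 for zinc finger genes and 5.33 and 5.67 for olfactory receptors. They were 6.67 in each group for interferon-stimulated genes and 1 in each for clustered protocadherins. No list differed in these counts past the threshold (exact permutation tests, smallest adjusted p = 0.282 over 48).

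The siRNA libraries are titled H4K20me3 while their file names carry H3K4me3. Their Jaccard index was 0.209 to 0.371 with every H4K20me3 library of the knockout experiment and 0.0397 to 0.0481 with every H3K4me3 library, so that the lowest of the former exceeded the highest of the latter by 0.161. A swap with the H3K4me3 antibody is therefore unlikely to explain the knockdown result. Antibodies not used in this series could not be compared.

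The 6 libraries of a comparison can be divided 3 against 3 in 10 ways, too few for a share under 0.05, and in each comparison the real division is set beside the highest of the other 9. Genes lost or gained numbered 583 against 15 for H4K20me3 in the knockout, 324 against 16 for H3K4me3 and 14 against 7 after siSMYD3. Regions lost or gained numbered 15001 against 163, 2166 against 76 and 143 against 113. Gene lists past the threshold numbered 4 against 0, 3 against 1 and 0 against 0. The real division gave the highest value in 1 of 10 ways, except for lists after siSMYD3, where all 10 gave 0.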
